A study of Homo sapiens with 12 samples.

How the data were processed

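RNA from 3 human cell lines in culture was compared on 12 arrays, each hybridised with 2 lines, 1 in Cy3 and 1 in Cy5. Per the labels, RNA was extracted with a silica column kit, and cDNA was made from oligo(dT) priming with dye-coupled dCTP. Each comparison of 2 lines had 4 arrays, 2 in either dye orientation. The arrays of each comparison stood on a slide of their own, so slide and comparison cannot be told apart from those 4 arrays alone. Any pair of lines could also be compared through the arrays of the other 2 comparisons, which stood on other slides.

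Per the file headers, the scanner files hold the mean and median pixel intensity of each spot in each channel, as quantified by ImaGene 9.0, with no background correction, logarithm or normalization. The medians were used only to mark saturated spots, at 65535. The deposited scanner files also hold a spot flag, recorded as another kind of value (other), whose codes the files do not explain. Spots with code 2 made up 12.5 to 25.3% of an array and spots with code 3 made up 5.27 to 12.1%. The authors also deposited a table of log2 ratios with 1 value per probe and array. Comparison with the scanner intensities settled that these are log2 values, that each array is centred near 0 (medians from -0.0265 to 0.0066) and that dye-swapped arrays were already turned to the same direction. The authors' method of background correction and normalization is not stated. Their ratios correlated across probes with those computed here at r from 0.994 to 0.999 per array. Probes are not independent replicates.

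The scanner intensities were the starting point. They hold no local background, so background was corrected from the distribution of foreground intensities (normexp, offset 50), and each array was normalized by loess with control spots given no weight. No scaling between arrays was applied. The arrays held 45220 spots, of which 1844 were controls. Spots of the same probe were averaged, which left 41000 probes. A current gene symbol was given to 24072 probes through their RefSeq accession, and 2518 carried a symbol that was already current. A further 3219 kept the symbol of the file and 11191 had none. A gene was counted through its probe of highest mean intensity over the 12 arrays, which gave 19977 genes.

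Ratios were turned to resistant over sensitive, or to 7SD over 7AS, by the dyes in the labels. A linear model was fitted to each probe over all 12 arrays with limma 3.58.1 in R 4.3.3, with 1 term for each of the 3 comparisons and 1 probe-specific dye term, which left 8 residual degrees of freedom. Moderated tests were two-sided, p values were adjusted by Benjamini and Hochberg over the 41000 probes within each comparison, and the threshold was 0.05. The dye term passed that threshold for 10610 probes (25.9%). Each numbered array was taken as 1 replicate, since the series text speaks of independently grown passages. The same text also speaks of technical replicates, so the spread between arrays that the tests measure may be partly technical. Python 3.11.15 with pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the plots.

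The comparisons, the test, 35 gene lists from textbook knowledge, the rule for the genes to be named and all alternatives but 1 were chosen before the data were examined. The lists held 942 entries, of which 936 (99.4%) had a probe. Each list was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes. Named genes were the 8 largest rises and the 8 largest falls past the threshold with the same sign on all 4 arrays and a signal above background in the brighter line. To these were added up to 4 members with the smallest adjusted p of each list past its test, and 18 fixed genes given whatever their result. Clone-type names, genes on the Y chromosome and the X-inactivation RNA were left out of the named genes. Background was the 95th percentile of 153 negative-control spots per channel and array. A fold was given as a lower bound where the dimmer line was not above background on any of the 4 arrays, or the brighter line was saturated on all of them.

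The procedure was checked on simulated data. Changes of 1 log2 unit were placed in 100 probes and of 2 log2 units in another 100, for each comparison in turn. In the 3 comparisons 63 to 74% of the smaller changes and 98 to 99% of the larger ones were recovered, with 6 to 16 unchanged probes called.

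The alternatives were no background correction, median centring in place of loess, quantile scaling of mean intensities after loess, and only probes above background. Others gave no weight to spots with a scanner mark or saturation, averaged all probes of a gene, left out the dye term or fitted the closed loop with 2 parameters. Further ones used only the other 2 comparisons, used only the comparison's own 4 arrays, added a replicate block or averaged dye-swapped arrays before the fit. The rest applied an intensity trend in the moderated test, took the authors' ratios, left out each array in turn, or estimated the correlation of each list. A separate dye term for each comparison was added after the data had been seen. Without marked or saturated spots, genes that lacked a value on any array were dropped from the list tests. Lists could then hold fewer members, and a list with too few left could not be retested. Subtraction of a local background had been planned and was not run, because the files hold none. The number of arrays limits the precision, and the median standard error of a log2 ratio was 0.16.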

Results

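Gene expression was measured in a human ovarian cancer cell line, SKOV3-13, and in 2 drug-resistant sublines, KH092-7SD and KH092-7AS, called 7SD and 7AS below. SKOV3-13 was sensitive to daily oral low-dose topotecan, a topoisomerase I poison, given with pazopanib, an inhibitor of the VEGF, PDGF and KIT receptor kinases. The sublines were grown out of tumours in animals that had been treated over a long period with topotecan at 1 mg/kg together with pazopanib at 150 mg/kg, 7SD from a solid tumour and 7AS from tumour cells in ascites. All RNA came from cells in culture. Each pair of lines was hybridised together on 4 arrays with 2 colours, so there were 12 arrays, and each array was counted as 1 replicate. The median intensity per array ranged from 1026 to 2990 in Cy3 and from 1515 to 3327 in Cy5. Between 76.1 and 89.5% of probes lay above the negative controls in Cy3, and 81.4 to 90.7% in Cy5. Values below are log2 ratios with the standard error (SE) of the limma model, with n = 4 arrays per comparison, and p values are adjusted for all probes or lists tested. Each list test past the threshold is followed by its p with an estimated correlation. With the signs of some arrays turned, as many lists passed in 4 of 8 splits for 7SD over SKOV3-13, in 6 of 8 for 7AS over SKOV3-13 and in 1 of 8 for 7SD over 7AS, the real split included. Fry passed no list in 7SD over SKOV3-13 (smallest adjusted p = 0.0625). In 7AS over SKOV3-13 it passed the mesenchymal (adjusted p = 0.00264), interferon, Wnt and ribosomal (0.0193 each) and inflammatory (0.0414) lists. The ovarian lineage list passed fry there too (0.0158), but not camera. In 7SD over 7AS fry passed the mesenchymal (1.7e-04), epithelial (0.00419), stemness (0.00689) and matrix (0.0382) lists. The other list calls did not pass fry.

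The comparison of 7SD with SKOV3-13 asks which genes differed between a resistant subline from a solid tumour and its sensitive parent. The small heat shock protein genes CRYAB and HSPB2, which lie next to each other in the genome, rose by 5.37 (SE 0.34) and 5.18 (SE 0.23), that is 41.4-fold and 36.2-fold. GASK1B rose 42.6-fold, GTSF1, a germline piRNA pathway gene, 33.0-fold, and TKTL1, a transketolase-like gene, 29.1-fold. The cancer-testis antigen GAGE7 was at least 24.4-fold higher, with saturated spots in 7SD. Genes of the SPANX family, cancer-testis antigens of sperm, fell, with ratios of -5.33 (SE 0.15) for SPANXD, saturated in SKOV3-13 on 2 of 4 arrays, and -4.79 (SE 0.19) for SPANXB1, and SPANXA1 was at least 36.3-fold lower, with saturated spots in SKOV3-13. GAGE and SPANX genes are nearly identical within each family, so it is uncertain which members the probes measured.

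Other large rises were the membrane mucin MUC15, at least 23.1-fold, which was not above background in SKOV3-13, and CNTNAP1 (4.47, SE 0.22), which was above background in SKOV3-13 on 3 of 4 arrays. EVI2A fell by 3.94 (SE 0.17), with 7SD above background on 2 of 4 arrays, and its neighbour EVI2B fell by 2.67 (SE 0.19), with 7SD above background on 3. UGT1A6, a glucuronosyltransferase, fell by 2.75 (SE 0.27), and its probe may be shared by other UGT1A transcripts. Among the 27 drug metabolism enzymes measured, 9 rose and 3 fell (12 and 5 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.0836), though it did with only probes above background (0.00522).

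Of 21 target genes of NRF2, the transcription factor of the oxidative stress response, none rose and 3 fell (0 and 7 adjusted over the list alone). The list was lower as a whole (p = 2.4e-05), with adjusted p = 0.965 with an estimated correlation. The aldo-keto reductases AKR1C1 and AKR1C3, which are close in sequence and not fully separable by probes, fell, with ratios of -2.82 (SE 0.58) and -2.73 (SE 0.60). SRXN1, a sulfiredoxin, fell by 0.57 (SE 0.14), and TXNRD1, thioredoxin reductase, had a ratio of -0.95 (SE 0.31) that did not pass (adjusted p = 0.149). Adjusted p rose to 0.126 for AKR1C1 without array 3 (0.108 without array 4), to 0.175 for AKR1C3 without array 3 (0.0751 and 0.140 without arrays 2 and 4) and to between 0.0805 and 0.186 for SRXN1 without any 1 array. Without marked or saturated spots none of the 3 passed (adjusted p = 0.0797, 0.104 and 0.0626), though their ratios stayed at -2.52, -2.48 and -0.63. The list did not pass either (adjusted p = 0.223).

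Of 41 interferon response genes, 5 rose and none fell (7 and 1 adjusted over the list alone), and the list was higher as a whole (p = 0.00464; adjusted p = 0.965 with an estimated correlation). BST2, a tethering factor that holds virions at the membrane, rose by 4.35 (SE 0.30), IFITM1 by 2.47 (SE 0.36), GBP1 by 1.37 (SE 0.18) and IFI44 by 0.77 (SE 0.14), with IFI44 above background in SKOV3-13 on 1 of 4 arrays. Of 35 inflammatory cytokines and NF-kB targets, 8 rose and 1 fell (9 and 1 adjusted over the list alone), and this list too was higher (p = 0.00853; adjusted p = 0.965 with an estimated correlation). The chemokine CCL20 rose by 3.81 (SE 0.34) on the log2 scale, IL32 4.25-fold, the adhesion molecule ICAM1 2.49-fold, the apoptosis inhibitor BIRC3 2.37-fold and the neutrophil chemokine CXCL8 3.36-fold (1.75, SE 0.43). Without array 1 the interferon list did not pass (adjusted p = 0.127), and without any 1 array CXCL8 did not (adjusted p from 0.118 to 0.185). Without marked or saturated spots the interferon list (adjusted p = 0.223), IFI44 (0.66, adjusted p = 0.537) and CXCL8 (1.71, adjusted p = 0.270) did not pass. With dye-swapped arrays averaged CXCL8 did not either (adjusted p = 0.196).

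Among the genes of the drugs' targets and of resistance, none but CXCL8 passed in 7SD. TOP1, the topotecan target, had a ratio of -0.48 (SE 0.15, adjusted p = 0.131), SLFN11, a sensitiser to replication damage, 0.47 (SE 0.19), the efflux pump ABCG2 -0.09 (SE 0.15) and the receptor PDGFRB 0.87 (SE 0.26, adjusted p = 0.0984). ABCB1, the gene of P-glycoprotein, was not above background in SKOV3-13 and had a ratio of 0.33 (SE 0.15). Ratios were 0.14 for TDP1, 0.17 for KDR, 0.03 for FLT1, -0.65 for PDGFRA, -0.07 for KIT, -0.05 for FGFR1, -0.67 for VEGFA and -0.31 for ERBB2. They were 0.04 for CDH1, 0.47 for VIM, 0.07 for MUC16 and 0.55 for ALDH1A1. None of the 25 camptothecin target and repair genes, 19 ABC drug transporters and 16 pazopanib target kinases passed (p of the lists 0.793, 0.963 and 0.793). Adjusted over the list alone, 0, 1 and 2 of them did.

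In limma's test 879 of 19977 genes (4.40%) changed, of which 627 (71.3%) rose and 252 fell. Of these 361 rose and 84 fell at least 2-fold, and 57 rose and 4 fell at least 8-fold. Every named gene past the threshold had the same sign on 4 of 4 arrays, which was a condition for the largest rises and falls. The count was 575 without a dye term, 1482 with the loop model, 1385 from the comparison's own 4 arrays and 307 from the arrays on the other slides. Without array 2, 3 or 4 it was 564, 537 or 548. From the arrays on the other slides GBP1 (0.83, adjusted p = 0.229) and IFITM1 (1.57, adjusted p = 0.313) had smaller ratios and did not pass. The calls of AKR1C1 (-3.02), AKR1C3 (-3.04), SRXN1 (-0.42), IFI44 (0.64), ICAM1 (1.06), BIRC3 (0.96) and CXCL8 were also lost there. The errors of the other sets add up in that estimate, and the ratios of AKR1C1 and AKR1C3 were no smaller.

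The comparison of 7AS with SKOV3-13 asks the same of a subline from ascites cells. Cancer-testis antigens were among the largest rises: GAGE7 was at least 49.2-fold higher, with saturated spots in 7AS, and MAGEA1 (5.06, SE 0.13), MAGEA4 (4.95, SE 0.15) and MAGEA9 (4.79, SE 0.13) rose 27.6-fold to 33.5-fold. GTSF1 rose 34.2-fold, CRYAB 23.7-fold (4.56, SE 0.34), TKTL1 23.1-fold and CYP1B1, a cytochrome P450 enzyme, 23.1-fold (4.53, SE 0.15). SPANXD (-6.09, SE 0.15), SPANXA1 (-5.85, SE 0.17) and SPANXB1 (-4.37, SE 0.19) fell. FLRT2, an adhesion and guidance protein, fell by 5.25 (SE 0.14), with 7AS above background on 3 of 4 arrays. UGT1A6 (-4.87, SE 0.27), EMP1 (-3.98, SE 0.41), the secreted laminin-related NTN4 (-3.84, SE 0.14) and APBB1IP (-3.74, SE 0.13) also fell. Members of the MAGEA family are also close in sequence.

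Of 28 mesenchymal markers, 1 rose and 8 fell (2 and 11 adjusted over the list alone), and the list was lower (p = 0.00417; adjusted p = 0.166 with an estimated correlation). Among those that fell were the receptor kinase AXL (-1.29, SE 0.19), TGFBI (-1.13, SE 0.23) and TPM1 (-1.30, SE 0.27). Of 20 fibroblast markers, which share 2 genes with that list, none rose and 3 fell (1 and 3 adjusted over the list alone; p of the list 0.831). Of 30 Wnt signalling genes, 2 rose and 5 fell (3 and 9 adjusted over the list alone), and the list was lower (p = 0.0282; adjusted p = 0.611 with an estimated correlation). Without array 3 or 4 the Wnt list did not pass (adjusted p = 0.0757 and 0.226), and without array 1 TPM1 did not (adjusted p = 0.0687). With dye-swapped arrays averaged TGFBI did not pass (adjusted p = 0.0570), and without marked or saturated spots neither the mesenchymal nor the Wnt list did (adjusted p = 0.0950 and 0.143), nor the Wnt list with only probes above background (0.158). WNT5A fell by 2.98 (SE 0.21), with 7AS above background on 2 of 4 arrays, and so did the Wnt antagonist DKK1 (-3.06, SE 0.43), the receptor FZD2 (-1.30, SE 0.21) and MYC (-0.81, SE 0.14).

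Of the 41 interferon response genes, 9 rose and none fell (21 and 0 adjusted over the list alone), with p = 7.8e-08 and adjusted p = 0.592 with an estimated correlation. BST2 rose 14.1-fold (3.81, SE 0.30), GBP1 2.95-fold, XAF1 1.99-fold and IFI44, above background in SKOV3-13 on 3 of 4 arrays, 1.68-fold. Of the 35 inflammatory cytokines and NF-kB targets, 11 rose and 1 fell (12 and 5 adjusted over the list alone; p = 0.00737), with adjusted p = 0.611 with an estimated correlation. CCL20 rose 9.23-fold (3.21, SE 0.34), BIRC3 3.24-fold, ICAM1 2.33-fold, IL32 3.18-fold and CXCL8 3.19-fold. CXCL8 did not pass without array 1, 2 or 4 (adjusted p = 0.160, 0.168 and 0.0549), nor with dye-swapped arrays averaged (adjusted p = 0.143). Without marked or saturated spots CXCL8 (log2 ratio 1.68, adjusted p = 0.0584), IFI44 (log2 ratio 0.78, adjusted p = 0.0974) and the inflammatory list (adjusted p = 0.0875) did not pass.

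The 21 NRF2 targets were lower as a list (p = 0.00224; adjusted p = 0.592 with an estimated correlation), with 5 that fell and none that rose (8 and 0 adjusted over the list alone). FTH1, the ferritin heavy chain, fell by 1.58 (SE 0.24), as did AKR1C1 (-2.97, SE 0.58), AKR1C3 (-2.83, SE 0.60) and TXNRD1 (-1.15, SE 0.31). Of 41 ribosomal protein genes, 8 fell and none rose (11 and 1 adjusted over the list alone; p = 1.2e-05), with adjusted p = 0.592 with an estimated correlation. Examples are RPS4X (-0.65, SE 0.12), RPS15 (-0.92, SE 0.18), RPL4 (-0.76, SE 0.17) and RPS23 (-0.59, SE 0.16). Of 24 cholesterol biosynthesis genes, 1 rose, the sterol dehydrogenase NSDHL (0.61, SE 0.12), and none fell (1 and 0 adjusted over the list alone). The list was higher (p = 5.2e-04; adjusted p = 0.611 with an estimated correlation), and the next members were HMGCS1 (0.66, SE 0.22), HSD17B7 (0.57, SE 0.20) and SC5D (0.48, SE 0.17), none of which passed. With 1 array left out, adjusted p went above 0.05 for TXNRD1 (up to 0.231, arrays 1, 3 and 4), AKR1C3 (up to 0.0837, arrays 1, 3 and 4), AKR1C1 (0.0543, array 4), NSDHL (0.0593, array 4) and the cholesterol list (0.0798, array 2). It did so too for RPS23 (up to 0.162, any array), RPL4 (up to 0.0908, arrays 2 and 4) and RPS15 (0.0567, array 1). Without marked or saturated spots TXNRD1 (-1.22, adjusted p = 0.265), RPS4X (-1.35, adjusted p = 0.0853) and RPS23 (-0.57, adjusted p = 0.170) did not pass. Nor did the NRF2 and cholesterol lists (adjusted p = 0.763 and 0.0695), and the ribosomal list could not be retested.

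Among genes of the drugs' targets and of resistance, TOP1 fell by 0.56 (SE 0.15, adjusted p = 0.043), and ABCB1 rose 1.99-fold (0.99, SE 0.15, adjusted p = 6.6e-04), from a level above background in SKOV3-13 on 2 of 4 arrays. SLFN11 rose by 0.94 (SE 0.19) and ALDH1A1, a retinaldehyde dehydrogenase, by 0.88 (SE 0.20). The pazopanib targets PDGFRA (-1.08, SE 0.29) and FGFR1 (-0.65, SE 0.12) fell, as did the receptor ERBB2 (-0.72, SE 0.18). The other fixed genes did not pass, with ratios of 0.05 for TDP1, -0.23 for ABCG2, 0.15 for KDR, -0.04 for FLT1, -0.53 for PDGFRB and -0.00 for KIT. They were -0.46 for VEGFA, -0.16 for CDH1, 0.93 for VIM (SE 0.33, adjusted p = 0.127) and 0.02 for MUC16. With 1 array left out, adjusted p went above 0.05 for TOP1 (0.175, 0.250 and 0.0806 without arrays 2, 3 and 4), PDGFRA (up to 0.241, arrays 1, 3 and 4) and ERBB2 (up to 0.159, arrays 1, 3 and 4). It did so for ALDH1A1 (up to 0.105, arrays 1, 2 and 3) and SLFN11 (0.0638, array 4). With the mean over all probes of a gene neither PDGFRA (-0.35, adjusted p = 0.113) nor FGFR1 (-0.36, adjusted p = 0.102) passed. Without marked or saturated spots TOP1 (-0.26, adjusted p = 0.558), ALDH1A1 (0.47, adjusted p = 0.377) and PDGFRA (-1.06, adjusted p = 0.0840) did not pass. With dye-swapped arrays averaged PDGFRA (adjusted p = 0.116) and ALDH1A1 (adjusted p = 0.0513) did not. Of the 25 camptothecin target and repair genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone), and of the 19 ABC transporters, 2 rose and 2 fell (3 and 2 adjusted over the list alone). Of the 16 pazopanib target kinases, none rose and 3 fell (0 and 4 adjusted over the list alone), and none of these 3 lists passed (p of the lists 0.907, 0.907 and 0.0934). The pazopanib kinase list passed without array 2 (adjusted p = 0.0156) and with only probes above background (0.0140).

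In limma's test 1566 genes (7.84%) changed, 757 up (48.3%) and 809 down, of which 321 rose and 264 fell at least 2-fold. The balance turned with the choice of fit, with 407 up and 258 down from the arrays on the other slides, 471 and 408 without a dye term, and 378 and 324 from the comparison's own 4 arrays. Median centring moved it further towards falls, with 651 up and 973 down. Named genes past the threshold had the same sign on 4 of 4 arrays, except NSDHL, RPS4X, PDGFRA and ERBB2 on 3 and RPL4 on 2. For the largest rises and falls this was a condition of the choice. The count was 879 without a dye term, 3108 with the loop model, 702 from the comparison's own 4 arrays and 665 from the arrays on the other slides. From the arrays on the other slides RPS4X (-0.06, adjusted p = 0.936), AXL (-0.76, adjusted p = 0.195), PDGFRA (-0.59, adjusted p = 0.630) and ALDH1A1 (0.59, adjusted p = 0.412) had smaller ratios and did not pass. The calls of FTH1, AKR1C1, AKR1C3, TXNRD1, TGFBI, TPM1, NSDHL, MYC, RPL4, RPS23, SLFN11, FGFR1, CXCL8 and ERBB2 were also lost there. The errors of the other sets add up in that estimate, and not all of these ratios were smaller. Without array 1, 3 or 4 the count was 968, 964 or 1041, with 506 up and 462 down, 530 and 434, and 527 and 514. Without array 2 it was 1335, with 528 up and 807 down. RPL4 turned direction and no longer passed (0.28, adjusted p = 0.755) when spots with a scanner mark or saturation had no weight.

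**Figure D1:**
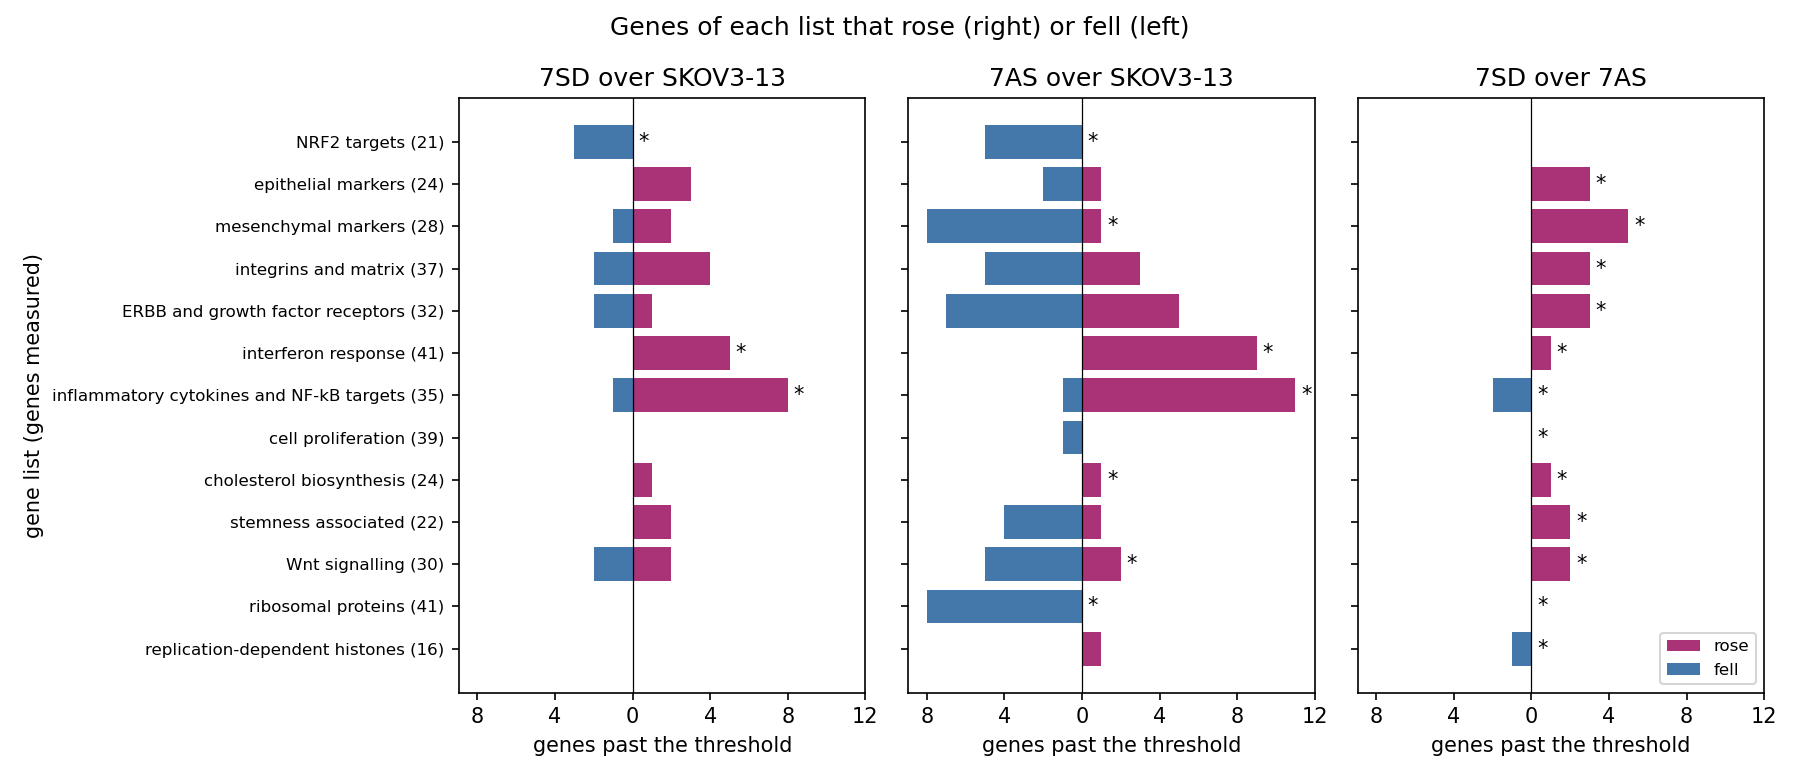
Number of genes of each list that rose (bars to the right) or fell (bars to the left) past the threshold in each comparison, for the 13 lists that passed camera's preset-correlation test in at least 1 comparison. The number after each name is the genes measured, and a star marks a list that passed, such as the interferon response in 7AS over SKOV3-13 with 9 genes up and 0 down.

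The direct comparison of 7SD with 7AS asks how the 2 resistant sublines differed from each other. The proteoglycan VCAN rose 13.5-fold (3.76, SE 0.16), fibronectin FN1 8.77-fold (3.13, SE 0.20), the epithelial adhesion gene EPCAM 8.65-fold (3.11, SE 0.18) and N-cadherin CDH2 3.72-fold (1.90, SE 0.16) in 7SD over 7AS. GASK1B rose 30.9-fold, FLRT2 was at least 18.5-fold higher, since it was not above background in 7AS, and IGFBP3 rose by 3.59 (SE 0.61), ANKRD1 by 3.41 (SE 0.42) and SAMSN1 by 3.26 (SE 0.23). In 7AS, the dimmer line, GASK1B, ANKRD1 and EPCAM were above background on 3 of 4 arrays and SAMSN1 on 2. PASD1, another cancer-testis antigen, was at least 9.59-fold lower in 7SD, where it was not above background. Others that fell were FGF5 (-1.89, SE 0.15), TXNIP (-1.81, SE 0.35), RYR2 (-1.69, SE 0.18), ASB4 (-1.45, SE 0.17) and LDOC1 (-1.32, SE 0.13). GAGE7 had a ratio of -1.56 (SE 0.15) with saturated spots in 7AS on 3 of 4 arrays. Without marked or saturated spots its ratio was -1.58 and did not pass (adjusted p = 0.164). PTPRD fell by 1.29 (SE 0.18), with 7SD above background on 2 of 4 arrays. TXNIP did not pass without array 1, 2 or 3 (adjusted p up to 0.146), nor IGFBP3 without array 1 (adjusted p = 0.0764), and with dye-swapped arrays averaged neither passed (adjusted p = 0.192 and 0.149).

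Of 28 mesenchymal markers, 5 rose and none fell (9 and 0 adjusted over the list alone), and this was the list call that held with an estimated correlation (p = 2.6e-07; adjusted p = 0.00645 with an estimated correlation). Beside FN1 and CDH2 these included TGFBI (1.13, SE 0.23) and CCN2 (0.99, SE 0.21). Of 37 integrin and matrix genes, 3 rose and none fell (4 and 0 adjusted over the list alone; p = 0.0023), with adjusted p = 0.410 with an estimated correlation, and these were VCAN, FN1 and FBN1 (0.91, SE 0.18). LAMA4 had a ratio of 0.75 (SE 0.21) that did not pass. Of 20 fibroblast markers, 3 rose and none fell (3 and 0 adjusted over the list alone; p of the list 0.0800), and this list shares 2 genes with the mesenchymal and 8 with the matrix list. Of 24 epithelial markers, 3 rose and none fell (5 and 1 adjusted over the list alone; p = 0.0149), with adjusted p = 0.345 with an estimated correlation. They were EPCAM, the tight junction gene CLDN4 (2.76, SE 0.20), above background in 7AS on 1 of 4 arrays, and the protease inhibitor SPINT1 (1.20, SE 0.24), while CLDN7 had a ratio of -0.82 (SE 0.22) that did not pass. With 1 array left out, adjusted p went above 0.05 for TGFBI (up to 0.124, arrays 1, 2 and 3), CCN2 (up to 0.177, any array), FBN1 (up to 0.172, arrays 1, 3 and 4), SPINT1 (up to 0.15, arrays 1, 3 and 4) and the epithelial list (0.0612, array 4). The fibroblast list passed without array 3 (adjusted p = 0.0170), and the epithelial list did not without marked or saturated spots (adjusted p = 0.136) or with only probes above background (0.376). With dye-swapped arrays averaged TGFBI, FBN1 and SPINT1 did not pass (adjusted p = 0.167, 0.124 and 0.123).

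Interferon response genes were lower in 7SD as a list (median of 41 genes -0.29, p = 6.0e-07; adjusted p = 0.410 with an estimated correlation). The 1 member past the threshold went the other way: IFITM1, a membrane protein that restricts virus entry, rose by 1.77 (SE 0.36), and adjusted over the list alone 1 rose and 7 fell. GBP1, OAS1 and OASL had ratios of -0.73 (SE 0.18), -0.92 (SE 0.24) and -0.53 (SE 0.16) and did not pass. Of 35 inflammatory cytokines and NF-kB targets, the chemokines CXCL1 (-1.08, SE 0.22) and CXCL2 (-1.04, SE 0.17) fell and none rose (5 and 0 adjusted over the list alone). The list was lower (p = 0.0486; adjusted p = 0.605 with an estimated correlation), and BIRC3 (-0.74, SE 0.19) and PTGS2 (-0.58, SE 0.17) did not pass. With 1 array left out, adjusted p went above 0.05 for IFITM1 (up to 0.210, arrays 1, 3 and 4), CXCL1 (up to 0.10, arrays 1, 2 and 4) and the inflammatory list (0.602 and 0.259, arrays 1 and 2). With dye-swapped arrays averaged IFITM1 (adjusted p = 0.0860) and CXCL1 (adjusted p = 0.0863) did not pass, and CXCL2 did not with the mean over all probes (adjusted p = 0.0686). The inflammatory list also did not pass without marked or saturated spots (adjusted p = 0.611) or with only probes above background (0.105), the mean over all probes (0.0631), the loop model (0.172), the comparison's own 4 arrays (0.0867), a replicate block (0.0646), averaged dye swaps (0.102) or a dye term for each comparison (0.0765). OAS1 passed without array 1 (adjusted p = 0.0323) and BIRC3 without array 3 (adjusted p = 0.0379).

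Of 30 Wnt signalling genes, WNT5A, above background in 7AS on 1 of 4 arrays, rose by 2.22 (SE 0.21) and the ubiquitin ligase RNF43 by 0.76 (SE 0.14), and none fell (5 and 0 adjusted over the list alone; p = 0.0130, with adjusted p = 0.410 with an estimated correlation). DKK1 (1.73, SE 0.43) and WNT3 (0.61, SE 0.17) did not pass. Of 32 ERBB and growth factor receptor genes, 3 rose, among them IGFBP3, IGFBP7 (1.61, SE 0.18) and the receptor ROR1 (0.70, SE 0.15), and none fell (6 and 4 adjusted over the list alone; p = 0.0394, with adjusted p = 0.410 with an estimated correlation). Of 22 genes associated with stemness, EPCAM and ALDH1A3 (0.68, SE 0.14) rose and none fell (3 and 0 adjusted over the list alone; p = 0.0126, with adjusted p = 0.345 with an estimated correlation), while HES1 (0.62, SE 0.18) and NES (0.55, SE 0.19) did not pass. Of 16 replication-dependent histone genes, H1-2 fell by 0.99 (SE 0.20), also 1 adjusted over the list alone, and the list was lower (p = 1.1e-04; adjusted p = 0.410 with an estimated correlation). H2AC6 (-0.60, SE 0.26), H3C1 (-0.32, SE 0.14) and H2BC12 (-0.45, SE 0.20) did not pass. Adjusted p went above 0.05 with 1 array left out for RNF43 (up to 0.0834, arrays 1, 2 and 3), ROR1 (up to 0.223, arrays 1, 3 and 4), ALDH1A3 (up to 0.201, any array) and H1-2 (up to 0.143, arrays 1, 3 and 4). It did so for the ERBB list (0.0644 and 0.283, arrays 1 and 4), the Wnt list (0.0524, array 4) and the stemness list (0.0553 and 0.0629, arrays 2 and 4), while NES passed without array 1 (adjusted p = 0.0158). With dye-swapped arrays averaged RNF43, ROR1, ALDH1A3 and H1-2 did not pass (adjusted p = 0.0863, 0.0839, 0.114 and 0.0984), nor did ROR1 and ALDH1A3 with the mean over all probes (adjusted p = 0.381 and 0.223). The stemness list did not pass without marked or saturated spots (adjusted p = 0.219), nor the ERBB list with the mean over all probes (adjusted p = 0.166), the loop model (0.0642) or a replicate block (0.0636).

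For 3 more lists the member counts and the list test did not go together. Cholesterol biosynthesis genes were lower in 7SD as a list (p = 0.0154; adjusted p = 0.740 with an estimated correlation), while 1 member rose past the threshold and none fell. Adjusted over the list alone, 1 of these 24 genes rose and 1 fell, and NSDHL (-0.43, SE 0.12), HSD17B7 (-0.46, SE 0.20) and MVD (-0.41, SE 0.20) did not pass over all genes. Of 39 cell proliferation genes none passed in either count, and the list was higher (p = 0.0486; adjusted p = 0.900 with an estimated correlation), with ratios of 0.68 (SE 0.19) for CCNB2, 0.54 (SE 0.21) for PRC1, 0.64 (SE 0.38) for UBE2C and 0.39 (SE 0.25) for KIF23. Of 41 ribosomal protein genes none passed in either count, and the list was higher (p = 0.0211; adjusted p = 0.605 with an estimated correlation), with ratios of 0.68 (SE 0.18) for RPS15, 0.52 (SE 0.16) for RPS23, 0.35 (SE 0.14) for RPS20 and 0.34 (SE 0.14) for RPS14. Adjusted p went above 0.05 with 1 array left out for the ribosomal list (up to 0.143, arrays 1, 3 and 4), the proliferation list (0.0711 and 0.571, arrays 1 and 2) and the cholesterol list (0.785, array 2), and without array 2 both of these turned direction. Without marked or saturated spots the proliferation list did not pass either (adjusted p = 0.289) and the ribosomal list could not be retested. Nor did the proliferation list pass with the mean over all probes (0.0631), the loop model (0.0642), averaged dye swaps (0.0855) or a dye term for each comparison (0.0829), or the ribosomal list with median centring (0.494).

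Of the 18 fixed genes, PDGFRB rose by 1.76 (SE 0.26, adjusted p = 0.00233) and ABCB1 fell by 0.75 (SE 0.15, adjusted p = 0.0194) in 7SD against 7AS, with PDGFRB above background in 7AS on 2 of 4 arrays and ABCB1 in 7SD on 1. ABCB1 did not pass without array 1 or 2 (adjusted p = 0.144 and 0.101) or without marked or saturated spots (-0.84, adjusted p = 0.0858). With dye-swapped arrays averaged neither PDGFRB (adjusted p = 0.0712) nor ABCB1 (adjusted p = 0.120) passed, and from the arrays on the other slides neither did (adjusted p = 0.216 and 0.467). TOP1 had a ratio of 0.51 (SE 0.15) and FGFR1 of 0.44 (SE 0.12), and neither passed. Nor did TDP1 (0.03), ABCG2 (0.14), SLFN11 (-0.16), KDR (0.00), FLT1 (-0.29), PDGFRA (-0.06), KIT (0.03), VEGFA (0.04) and CXCL8 (-0.09). The pazopanib kinase list passed without array 3 (adjusted p = 0.0399) and with only probes above background (0.0266). The ratios of ERBB2 (0.28), CDH1 (0.13), VIM (-0.21), MUC16 (0.13) and ALDH1A1 (-0.03) did not pass either.

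In limma's test 279 genes (1.40%) differed between the sublines, 212 (76.0%) higher and 67 lower in 7SD. Of these 127 were higher and 30 lower by at least 2-fold. All named genes past the threshold had the same sign on 4 of 4 arrays, as the choice of the largest rises and falls required. The count was 182 with only probes above background, 171 without a dye term, 646 with the loop model, 101 from the arrays on the other slides and 141 with dye-swapped arrays averaged. Without array 1, 3 or 4 it was 173, 180 or 164. From the arrays on the other slides ASB4 (-0.27, adjusted p = 1.00), LDOC1 (-0.80, adjusted p = 0.112), CLDN4 (0.90, adjusted p = 0.470), IGFBP7 (0.87, adjusted p = 0.337) and GAGE7 (-1.01, adjusted p = 0.0584) had smaller ratios and did not pass. The calls of IGFBP3, TXNIP, PTPRD, SPINT1, TGFBI, CCN2, FBN1, ROR1, CXCL1, CXCL2, ALDH1A3, H1-2, ABCB1 and PDGFRB were also lost there. Errors of the other sets add up in that estimate, and not all of these ratios were smaller.

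**Figure D2:**
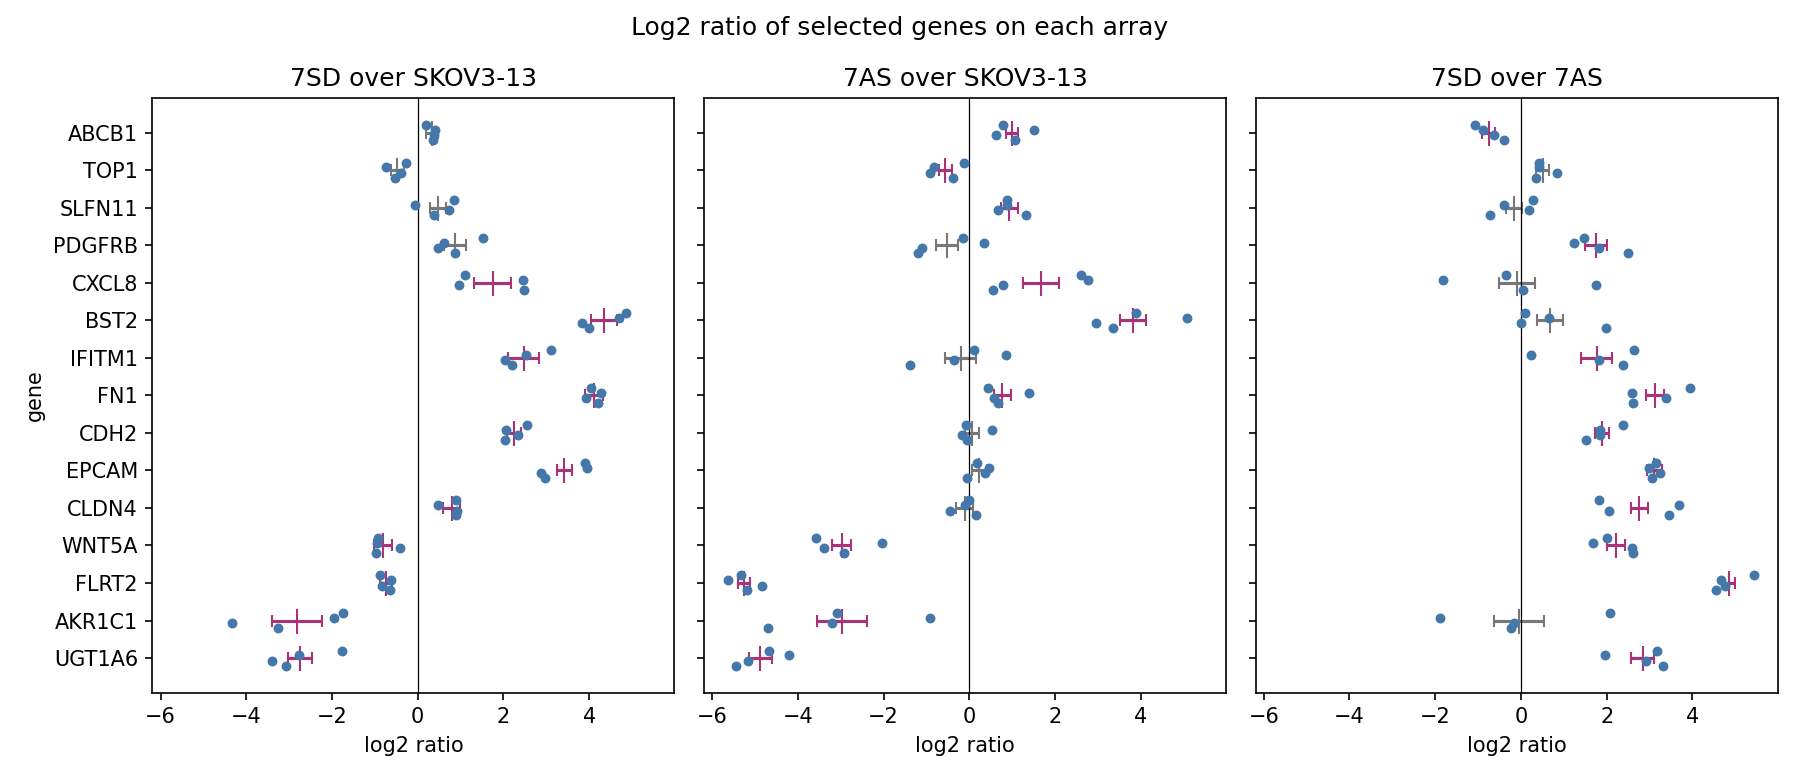
Log2 ratio (horizontal axis) of 15 named genes on each of the 4 arrays of a comparison (points), with the model estimate (tick) and its SE (bar), in purple where the adjusted p passed the threshold and grey where it did not. All 4 arrays of FN1, EPCAM and CDH2 lie to the right of 0 in 7SD over 7AS, and AKR1C1 lies on both sides of 0 there.

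Both sublines were then compared for shared changes. In both, 580 genes changed in the same direction, 394 up and 186 down, where independent lists of these sizes would share 23.8 and 10.2. Of the genes that rose in 7SD 62.8% also rose in 7AS, and of those that fell 73.8% also fell. Of the genes that changed in 7AS, 52.0% of those that rose and 23.0% of those that fell did the same in 7SD. CRYAB, GTSF1, TKTL1, GAGE7, BST2 and CCL20 rose in both, and SPANXD, SPANXA1, SPANXB1, UGT1A6, AKR1C1 and AKR1C3 fell in both. Against this, 3 genes went opposite ways: SH3RF2 (0.87 in 7SD, -0.64 in 7AS), PRICKLE2 (0.89, -0.60) and NEGR1, a neuronal adhesion gene (1.14, -1.30), each with a difference between the sublines in the direct comparison (adjusted p = 5.5e-05, 0.0018 and 7.3e-06).

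SKOV3-13 RNA stood on both sets of arrays, so chance values of the parent were shared between the comparisons. In 20 simulations of unchanged lines with shared parental passages, the ratios correlated at r = 0.50 across genes with a covariance of 0.0211 and no shared call. The measured values were r = 0.75 and a covariance of 0.138, and genes are not independent replicates. With 7SD arrays 1 and 2 set against 7AS arrays 3 and 4, 222 genes were shared (179 up, 43 down), and with the reverse split 207 (174 up, 33 down). In these splits r was 0.47 and 0.48, with a covariance of 0.110 in each. The simulation kept all arrays and shared passages, so its r cannot be set directly against that of the splits. The count of shared genes was 369 without a dye term and 1159 with the loop model, and without array 3 of 7SD over SKOV3-13 it was 382.

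**Figure D3:**
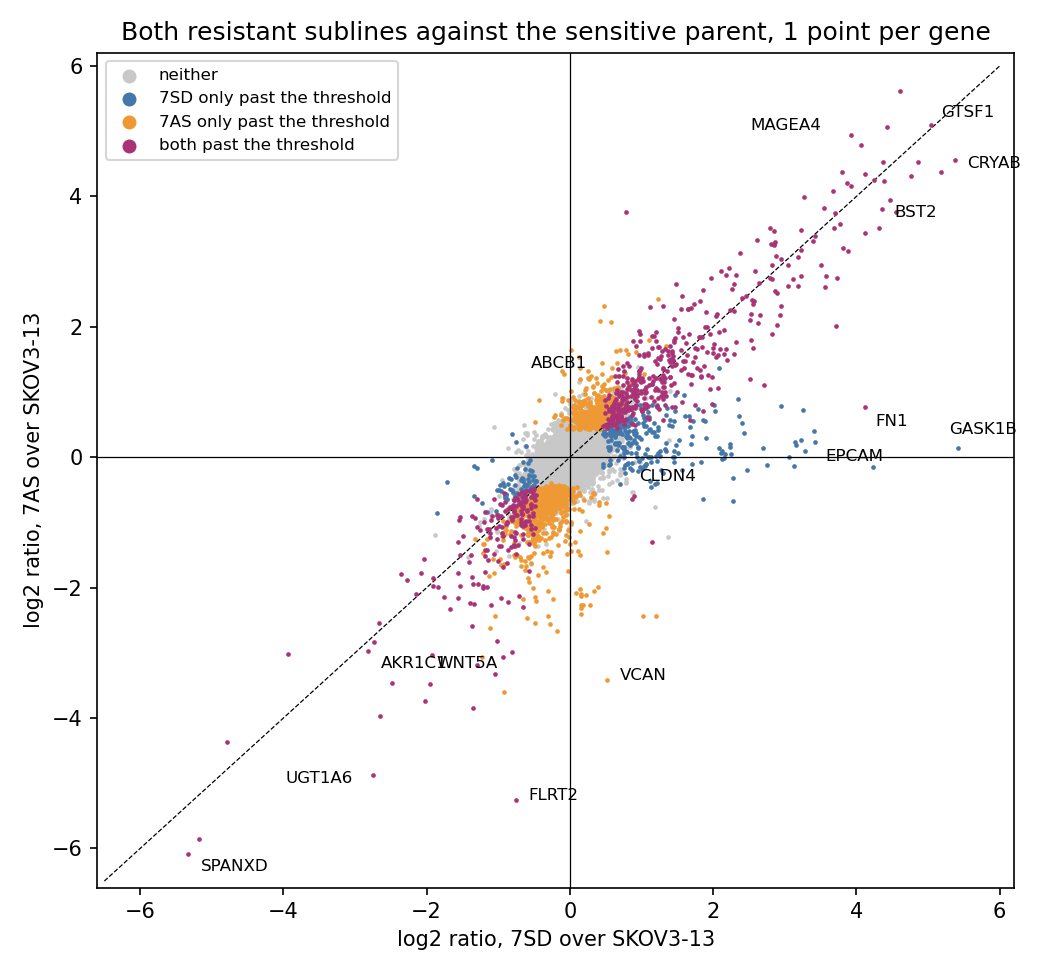
Log2 ratio of each gene in 7AS over SKOV3-13 (vertical axis) against 7SD over SKOV3-13 (horizontal axis), coloured by the comparisons in which limma's adjusted p passed the threshold, with the dashed line marking equal ratios. Genes such as CRYAB and SPANXD lie near that line, and FN1, EPCAM, GASK1B, VCAN and FLRT2 lie away from it.

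The 3 comparisons form a closed loop, so the ratio 7SD over SKOV3-13 divided by 7AS over SKOV3-13 can be set against the direct ratio 7SD over 7AS. No probe differed between these paths in limma's test after adjustment. An unadjusted p under 0.05 was found for 677 of 41000 probes (1.65%), fewer than independent arrays with no difference would give. If same-numbered arrays share passages, which the labels do not say, passage noise cancels around the loop and the test overstates its error. A count of 0 then does not show that the paths match. The count was also 0 under every alternative that was run. Over the 279 genes called in the direct comparison, the indirect and direct ratios correlated at r = 0.95 and 98.9% had the same sign. These genes were picked on the direct ratio, and noise of any shared passages would enter both paths, so this agreement may be too high. Simulated data with changes placed in 200 probes of 1 comparison alone had noise drawn for each array on its own. There 87 to 99 of all probes passed this test, a count not limited to the 200 changed ones. CLDN4 is a gene with a wide gap between the paths: its direct ratio was 2.76, against 0.79 in 7SD and -0.10 in 7AS over SKOV3-13.

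Markers of other cell types that a tumour or ascites could hold were also counted. Human probes see transcripts of the host animal only through cross-hybridisation, so these counts say little about carried-over host cells. None of the 26 leukocyte and 13 erythroid markers passed in any comparison, over all genes or adjusted over the list alone. Of 18 endothelial markers, 1 fell in 7AS and none passed elsewhere, in either count. Of 14 mesothelial markers, 1 fell in 7SD and 2 in 7AS against SKOV3-13, and 1 was higher in 7SD than in 7AS (adjusted over the list alone, 1 fell, then 1 rose and 3 fell, then 4 rose). Of 20 fibroblast markers, 2 rose and 1 fell in 7SD against SKOV3-13 (3 and 2 adjusted over the list alone). None of these 5 lists passed camera's test, with the smallest p at 0.0800 for fibroblast markers in 7SD over 7AS. The mesothelial list did pass with only probes above background, in 7AS over SKOV3-13 (adjusted p = 0.0140) and 7SD over 7AS (0.0238). The fibroblast list passed in 7SD over 7AS without array 3 (adjusted p = 0.0170), without a dye term (0.0432) and with the loop model (0.0372). In all, 22 of the 35 lists passed it in no comparison, among them hypoxia response, p53 targets, apoptosis regulators, unfolded protein response, glycolysis, oxidative phosphorylation and lysosome. Some of these did pass under another setting. The hypoxia list passed in 7SD over 7AS without array 3 or 4 (adjusted p = 0.0295 and 0.0228), with the mean over all probes (0.0324), without a dye term (0.0426), from the comparison's own 4 arrays (0.0399) and with a dye term for each comparison (0.0452). The lysosome list passed there with median centring (adjusted p = 0.0341). The unfolded protein response passed in 7SD over SKOV3-13 without array 1 (adjusted p = 0.0157) and in 7AS over SKOV3-13 without array 2 (adjusted p = 0.00893). The list of MHC class I and antigen presentation passed in 7SD over SKOV3-13 under 7 other settings (adjusted p from 0.00608 to 0.0407) and in 7AS over SKOV3-13 under 4 (0.00847 to 0.0436). Without array 2 the DNA damage, heat shock and TGF-beta lists also passed in 7AS over SKOV3-13 (adjusted p = 0.0182, 0.0216 and 0.0326). Of the lists past the threshold in another comparison, the ERBB list (adjusted p = 0.0326, without array 2), the histone list (0.000575, without array 2, and 0.0369, with the loop model) and the proliferation list (0.00611 and, in the other direction, 0.00059, without arrays 2 and 4) passed in 7AS over SKOV3-13. In 7SD over SKOV3-13 the ribosomal list did without array 3 (adjusted p = 0.0385), and the cholesterol list from the comparison's own 4 arrays (0.0194) and with averaged dye swaps (0.0407).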

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

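The interferon test on the other slides, all tests of the cancer-testis genes, the Fisher test included, and the separate dye term for each comparison were chosen after the results had been seen. The SE of a median in this section is over genes taken as independent, and is too small where genes of a list move together.

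NRF2 targets, a list fixed in advance, were lower as a list in both sublines, with 3 and 5 of 21 members that fell past the threshold and adjusted p = 0.965 and 0.592 with an estimated correlation. Signal shared among the AKR1C genes would leave the other genes near 0. Without the AKR1 genes the medians were -0.31 (SE 0.0763, 17 of 18 genes negative) in 7SD and -0.25 (SE 0.143, 14 of 18 negative) in 7AS. This goes against such signal as the whole cause if the genes are independent, and less clearly if they move together. Dye bias would turn the sign with the dye orientation. The medians of all 4 sets of arrays of 1 comparison and orientation were negative, the nearest to 0 at -0.28 (SE 0.247). The estimated correlation between genes of this list was 0.16, so the SEs are too small, and dye bias cannot be set aside on these values. A lower NRF2 activity in both sublines may account for the pattern, as a hypothesis that these data cannot test. A change in the cultured parent that both sets of arrays share stays open, as does chance, given the list counts below. Marked or saturated spots stay open too, since neither list call passed without them (adjusted p = 0.223 and 0.763). Genes missing on any array were then left out of the lists, so the loss of members and the spots themselves cannot be told apart.

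Interferon response genes were lower in 7SD than in 7AS as a list (adjusted p = 0.410 with an estimated correlation), while 1 of 41 members rose past the threshold and 0 fell. A difference between slides would not carry over to the other 2 comparisons, and there the list median was -0.20 (SE 0.108, 30 of 41 genes negative). Dye bias would turn the sign between orientations, and the medians were -0.26 (SE 0.121, 28 of 41 negative) and -0.30 (SE 0.104, 32 of 41 negative). Both sets of values keep the sign of the list, but the estimated correlation between genes of this list was 0.23, so their SEs are too small. Neither a difference between slides nor dye bias can be set aside on these values. IFITM1, the member that rose, had a ratio of 1.77. A difference in interferon signalling between the sublines may be set down as a hypothesis that these data cannot test, and a difference in culture state at harvest was not tested.

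Of 52 cancer-testis antigen genes, 32 changed the same way in both sublines. Signal shared between near-identical members cannot by itself join families of unrelated sequence, and 7 such families held genes changed in both. These families were chosen with their changes known, so their number is no test. Shared signal within a family may still raise the count of 32 genes. A difference between slides would leave the genes called in 1 comparison near 0 when that comparison is estimated from the other arrays. There the medians in the direction of the call were 2.88 (SE 0.255, 32 of 32 of the same sign) in 7SD and 3.40 (SE 0.344, 33 of 33) in 7AS. The families were picked after their changes in both comparisons had been seen, and the 32 genes called in 7SD were also called in 7AS. Each estimate thus rests on ratios that had a part in the choice, so these values cannot decide on a difference between slides. A heritable change of gene regulation in the selected cells may account for the pattern, as a hypothesis that these data cannot test. A different history of the parental culture in the laboratory stays open, because the same parent stands in both comparisons.

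Signs of some of the 4 arrays of a comparison were also turned, which gives 8 splits with the real one included, too few for a share under 0.05. For 7SD over SKOV3-13, 1 of 8 gave as many genes (879, highest other 0), and for 7AS over SKOV3-13 also 1 of 8 (1566, highest other 0). For 7SD over 7AS it was 2 of 8 (279, highest other 1292), and the split that gave 1292 follows the dye orientation, which points to a dye effect on that slide that the shared dye term left in. With a dye term for each comparison the count was 372. For genes changed in both sublines, 1 of 64 splits gave as many (580, highest other 0), but turned splits of either comparison left 0 genes to share, so this count adds nothing to those of the single comparisons. As many lists passed in 4 of 8 splits for 7SD (3, highest other 10), 6 of 8 for 7AS (7, highest other 16) and 1 of 8 for 7SD over 7AS (12, highest other 10). List calls at the preset correlation thus arose as readily in turned splits of the first 2 of these comparisons.

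Of 202 sets of 4 array values tested, 11 held an array far from the other 3, where chance gives about 1 in 20. In 7SD over SKOV3-13 these were GBP1 on array 3 (0.81, others 1.48 to 1.60), ABCB1 on array 1 (0.20, others 0.37 to 0.40) and KDR on array 2 (-0.23, others 0.29 to 0.32). The share of probes above background in Cy5 was 83.8% on array 1 of that comparison, against 84.0 to 84.1%. In 7AS over SKOV3-13 they were GAGE7 on array 4 (5.13, others 5.76 to 5.80) and CCL20 on array 2 (4.58, others 2.66 to 2.93). In 7SD over 7AS they were LDOC1 (-1.70, others -1.20 to -1.17) and TOP1 (0.85, others 0.35 to 0.43) on array 3, and FBN1 (1.22, others 0.77 to 0.85) and KIF23 (-0.31, others 0.53 to 0.69) on array 4. NES on array 1 had -0.32, against 0.82 to 0.87.

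Of 70 genes named against the parent, 18 also differed between the sublines in the direct test. Higher in 7SD were GASK1B (4.95), FLRT2 (4.85), UGT1A6 (2.84), APBB1IP (2.42), WNT5A (2.22), NTN4 (2.21), IFITM1 (1.77), PDGFRB (1.76), TPM1 (1.20) and TGFBI (1.13). The SPANX genes SPANXD (0.97) and SPANXA1 (0.94) were also higher. Lower in 7SD were GAGE7 (-1.56, with saturated spots in 7AS), GTSF1 (-1.18), MAGEA9 (-1.08), MAGEA1 (-0.82), MAGEA4 (-0.80) and ABCB1 (-0.75). For GTSF1 the ratios over the parent were nearly equal, 5.04 in 7SD and 5.10 in 7AS. Its direct difference was thus not seen through the arrays on the other slides, and the cause of this gap was not tested.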

How the results depend on the processing

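The separate dye term per comparison was added after the data had been seen. Without a dye term the counts of changed genes were 575 in 7SD over SKOV3-13, 879 in 7AS over SKOV3-13, 171 in 7SD over 7AS and 369 in both sublines, and with the loop model 1482, 3108, 646 and 1159. From the other array sets alone they were 307, 665 and 101, and from the comparison's own 4 arrays 1385 and 702 in the first 2. In the estimate from the other sets the error of 2 sets adds up, and some ratios were also smaller. Which of these lowered the counts was not tested. In 7SD over 7AS, only probes above background gave 182 and averaged dye swaps 141, which leave fewer genes or arrays. With 1 array left out the counts ranged from 537 to 595, 964 to 1335, 164 to 287 and 382 to 545, and the list calls from 18 to 29, against 22 with all arrays. List calls were 1 with an estimated correlation and 9 without marked or saturated spots, where 11 of 20 that could be retested were lost. Without these spots, genes missing on any array were dropped from the lists, so lost members may also have ended calls. A replicate block, which would pair same-numbered arrays, gave 812, 1441, 247 and 556 genes, with 20 list calls. It ended 6 of the 109 calls of named genes. The labels do not say that numbers mark a shared passage, and 4 of 6 correlations of deviations between sets had the sign of pairing at over 0.1. Deviations of dye-swapped arrays 1 and 2 correlated at 0.39 in 7SD over SKOV3-13, 0.53 in 7AS over SKOV3-13 and -0.13 in 7SD over 7AS. Whether they hold the same extracts stays open, and with dye swaps averaged the counts were 624, 1127, 141 and 417 genes in the same order as for the block. The loop closure stayed at 0 in all alternatives run. The cell proliferation list reversed in 7AS over SKOV3-13 without replicate 2 of that comparison (adjusted p = 0.00611; 5.9e-04 to 0.999 over the 4 arrays left out) and in 7SD over 7AS without its replicate 2 (0.571; 0.000649 to 0.571), where cholesterol biosynthesis also did (0.785; 4.3e-05 to 0.785). RPL4 reversed in 7AS over SKOV3-13 without marked or saturated spots (log2 ratio 0.28, adjusted p = 0.755). Where no reason is given, the cause was not tested. Of 2046 alternative values of the 109 named genes past the threshold, 237 no longer passed and 1 reversed, and 56 genes passed in all of theirs. Of 1336 values of the 72 others, 38 passed. Of 416 alternative values of the 22 list calls 65 no longer passed and 2 reversed. Scaling by quantiles left the ratios as they were by construction. Subtraction of a local background was not run, since the files hold none. Between 76.1 and 89.5% of probes per array lay above background in Cy3, and changes of the dimmer ones are limited to lower bounds.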

Other observations

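Cancer-testis antigens, genes normally active in the testis and reactivated in many tumours, were among the large changes in both sublines and in no list fixed in advance. The list of these genes was drawn up after the data had been seen, so its counts are not independent evidence. Of 52 such genes measured, 32 changed the same way in both sublines against SKOV3-13, 29 up and 3 down. That is 61.5% of them, against 2.75% of all other genes (odds ratio 56.4, Fisher exact p = 2.0e-36, with genes that are not independent of each other). All 7 SSX genes rose in both, with medians of 3.18 in 7SD and 3.08 in 7AS, as did 9 of 10 MAGEA genes (3.73 and 4.22), all 3 CSAG genes (2.88 and 3.09), all 3 GAGE genes (1.98 and 2.75) and both CT45 genes (1.46 and 1.79). MAGEA1 rose by 4.43 (SE 0.13) in 7SD and 5.06 (SE 0.13) in 7AS, CTAG1A by 4.38 (SE 0.20) and 4.23 (SE 0.20), and XAGE1 by 2.94 (SE 0.14) and 2.18 (SE 0.14). Other families changed less or fell: 3 of 4 SPANX genes fell in both, 2 of 8 MAGEB, 1 of 4 XAGE, 1 of 5 PAGE and 1 of 2 CTAG genes rose in both. None of the 3 MAGEC genes rose, nor the 1 CT47 gene, and MAGEC2 fell in 7AS (-0.45, SE 0.12). Probes within these families may be shared by near-identical members, so the counts of genes within a family may be too high. The 7 unrelated families with genes changed in both were chosen with their changes known.

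Drug metabolism enzymes, a list fixed in advance, held large changes of single genes in both sublines. CYP1B1 rose by 4.37 (SE 0.15) in 7SD and 4.53 (SE 0.15) in 7AS, and ALDH3A1 fell (-2.35, SE 0.21, and -1.79, SE 0.21), genes chosen after their values had been seen. GSTM3, a glutathione transferase chosen in the same way, rose by 1.72 (SE 0.20) in 7SD. In 7AS 5 of the 27 enzymes rose and 4 fell (11 and 5 adjusted over the list alone; p of the list 0.126), and without array 4 the list passed (adjusted p = 0.0231). MECOM, a transcription factor often amplified in ovarian cancer, fell in 7SD (-1.95, SE 0.20) and in 7AS (-3.47, SE 0.20), and it was also chosen after its values had been seen.

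Replicate arrays of the same dye orientation resembled each other more than those of opposite orientation. Across probes, ratios turned to the same direction correlated at 0.44 to 0.71 within an orientation. Between orientations r ranged from 0.05 to 0.25 for 7SD over SKOV3-13, from -0.03 to 0.30 for 7AS over SKOV3-13 and from -0.40 to -0.23 for 7SD over 7AS.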
